A study of Homo sapiens with 9 samples.

How the data were processed

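RNA was measured in 9 libraries of H1299, an established lung cancer cell line. The labels put 3 libraries in the group Vector (cells transduced with the lentiCRISPR v2 plasmid), 3 in KO1 and 3 in KO2, which are 2 monoclonal lines made by CRISPR editing of BCKDK. Total RNA was taken with TRIzol, libraries were made with a NEBNext Ultra kit and sequenced on a NovaSeq 6000, per the labels' protocols. The labels do not say that the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical. For BCKDK knockout in general the unit is the clone, with n = 2.

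The deposited table holds FPKM, that is reads scaled to exon length and library size, for 58735 genes, of which 23132 were listed at 0 in all 9 libraries. Reads were handled with CASAVA 1.6, HISAT2 2.0.5 and featureCounts 1.5.0-p3 on the human build hg38, per the submitters' processing notes. The order, the options, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. All gene identifiers were found in GENCODE 29 (Ensembl 94), and 99.95% of the gene names equalled the names there, so positions are from that annotation of hg38. Multiplying each FPKM value by the gene's merged exon length gave whole reads for 100.0% of the values in every library, within a tolerance of 0.02 reads. The recovered depth was 16002212 to 17090445 reads per library. The scaling already in the deposited FPKM equalled median-of-ratios size factors of these reads, with a ratio of 1.0 in each library. Depth was therefore nearly equal between libraries, and low genes carry few reads. Genes that overlap another gene or share sequence with close copies are uncertain, since reads could have been split or assigned to the wrong gene.

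The analysis fixed before the data were examined was a count test with a fallback for normalized values, and the fallback was used because the deposited values are FPKM. Values were taken as log2(FPKM + 1), and 16426 genes with a mean of at least 0.5 FPKM over the 9 libraries were fitted with limma 3.58.1 (trended empirical Bayes, R 4.3.3). All 9 libraries entered one fit with the group as the only term. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Every adjusted p for a gene below comes from this limma test unless another setting is named. The comparisons were KO1 against Vector, KO2 against Vector, KO2 against KO1 and the mean of both clones against Vector. Both clones share the Vector libraries, so the overlap and the correlation between the clones were set against 100 simulations of unchanged groups. In these the shared control was simulated too.

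A set of 45 gene lists with 1101 genes was fixed before the data were examined, and the 41 lists with at least 5 fitted genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, were run beside it. With an estimated correlation 0 lists were called in any comparison. At an unadjusted p under 0.05 it gave 5, 3 and 7 lists in KO1 against Vector, KO2 against Vector and KO2 against KO1, and fry called 18, 18 and 26. The estimated-correlation p is given where a list is described. Named genes follow a rule fixed at the same time. It takes the 4 genes of the series title, the 10 rising and 10 falling protein-coding genes with the largest smaller-of-both-clones change (mean of at least 5 FPKM, all 6 knockout libraries on one side of all 3 Vector libraries). It adds 4 rising and 4 falling genes per clone that also differed between the clones, and up to 2 rising and 2 falling members per described list with the smallest p in the mean of both clones. The lists described with members are the 21 called by camera in KO1, in KO2 or between the clones, and the 3 lists for branched-chain amino acid catabolism, the TCA cycle and oxidative phosphorylation. Which lists to describe was decided after the results were seen. Some genes that the rule picks are not reported here.

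The procedure was tested on simulated data. In the KO1 against Vector comparison of simulated reads with 16449 genes fitted, 28.4% of 67 genes changed 1.5-fold were called, 56.7% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, and 4% of 125 calls were false. Changes under 2-fold were thus often missed in this simulation. Only those 67, 67 and 66 genes were changed in it, whereas 34.1% of the fitted genes were called in the real KO1 comparison. The Benjamini-Hochberg cut is stricter where few genes change, so these shares do not carry over to the real comparison.

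Other settings covered the scaling, filters, pseudocount, test, threshold, replicate block and each library left out in turn. A further 5 were chosen after seeing the data: leaving out Vector replicate 3 and KO2 replicate 3 together, library weights, protein-coding genes alone, subtraction of the median of neighbouring genes within 5 Mb per library, and removal of each library's trend on GC content and exon length (natural splines with 4 degrees of freedom). Neighbours were protein-coding genes with a mean of at least 2 FPKM, with at least 10 of them required. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.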

Results

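Gene expression was measured by RNA sequencing in H1299 lung cancer cells with and without editing of BCKDK, the kinase that phosphorylates and inhibits the branched-chain ketoacid dehydrogenase complex. Control cells carried the lentiCRISPR v2 plasmid (Vector), and 2 monoclonal knockout lines, KO1 and KO2, were compared with them, with 3 libraries in each of the 3 groups. The series title links BCKDK to BCLAF1, MYC, HK2, aerobic glycolysis and resistance to Trametinib, a MEK inhibitor. The comparisons ask which transcripts differ between these knockout lines and Vector. Only the knockout lines are described as monoclonal, so effects of BCKDK editing and of single-cell cloning cannot be told apart against Vector. Recovered reads numbered 16369655, 16002212 and 16973059 in Vector replicates 1, 2 and 3. They numbered 16838601, 16858304 and 17090445 in KO1, and 16609669, 16654780 and 16267829 in KO2. Vector replicate 3 and KO2 replicate 3 stood apart from the other libraries of their groups. Chi-square per degree of freedom was 46.4 and 39.1 between Vector replicate 3 and the other Vector libraries, against 6.21 between those. It was 42.9 and 39.6 between KO2 replicate 3 and its group, against 2.47. The lowest value for a pair within a group was 2.35, which does not tell separate cultures from technical repeats.

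BCKDK transcript fell in every knockout library. BCKDK (ENSG00000103507, chromosome 16, 31106107 to 31112791 of hg38, plus strand) stood at 13.7, 12.9 and 17.5 FPKM in the Vector libraries, at 1.91, 2.06 and 1.67 FPKM in KO1 and at 0.628, 0.576 and 0.287 FPKM in KO2. The log2 fold change was -2.44 (SE 0.14, limma adjusted p = 3.63e-06) in KO1 and -3.39 (SE 0.14, limma adjusted p = 1e-06) in KO2. KO2 was lower than KO1 by a log2 difference of -0.95 (limma adjusted p = 0.00109). The 3 other genes of the title did not move alike. HK2, the hexokinase that takes glucose into glycolysis (ENSG00000159399, chromosome 2, 74833981 to 74893359), fell in KO2 from 14.6 ± 2.22 to 6.96 ± 0.0857 FPKM (SD, n = 3; log2 -0.96, SE 0.11, limma adjusted p = 0.00035) and measured 15.1 ± 0.801 FPKM in KO1 (log2 0.05, limma adjusted p = 0.747). The difference between the clones itself passed the test (log2 -1.01, limma adjusted p = 0.000243). MYC, the transcription factor (ENSG00000136997, chromosome 8, 127735434 to 127741434), measured 87.7 ± 9.07 FPKM in Vector, 58.4 ± 4.52 in KO1 and 43.5 ± 15.2 in KO2 (SD, n = 3). MYC fell in KO2 (log2 -1.06, SE 0.24, limma adjusted p = 0.0107), where KO2 replicate 3 gave the lowest of the 9 values. Without that library the MYC change in KO2 was -0.73 (limma adjusted p = 0.00307). In KO1 the MYC value of -0.58 missed the threshold (limma adjusted p = 0.093) and passed it without KO2 replicate 3 (0.00334), in a fit of the 6 KO1 and Vector libraries alone (0.00934) and with limma-voom (0.0488). Genes within 5 Mb of MYC had a median of -0.37 in KO1 and 0.05 in KO2. With that median subtracted MYC stood at -0.18 in KO1 (limma adjusted p = 0.639) and -1.07 in KO2 (0.014). BCLAF1, a splicing and transcription regulator (ENSG00000029363, chromosome 6, 136256627 to 136289851), measured 36.2 ± 7.55, 39.1 ± 0.404 and 36.8 ± 4.4 FPKM in Vector, KO1 and KO2. It passed the test in neither clone (log2 0.13 and 0.04, limma adjusted p = 0.558 and 0.871), and the sign turned negative in both without Vector replicate 3 (-0.05 and -0.14). Without both libraries that stood apart its value in KO2 was -0.23 and passed the test (limma adjusted p = 0.00388), as did -0.2 with library weights (0.0108). Its neighbours had medians of -0.01 in KO1 and -0.39 in KO2, and with these subtracted it stood at 0.07 in KO1 (limma adjusted p = 0.671) and at 0.49 in KO2, which passed in the other direction (0.0128).

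**Figure D1:**
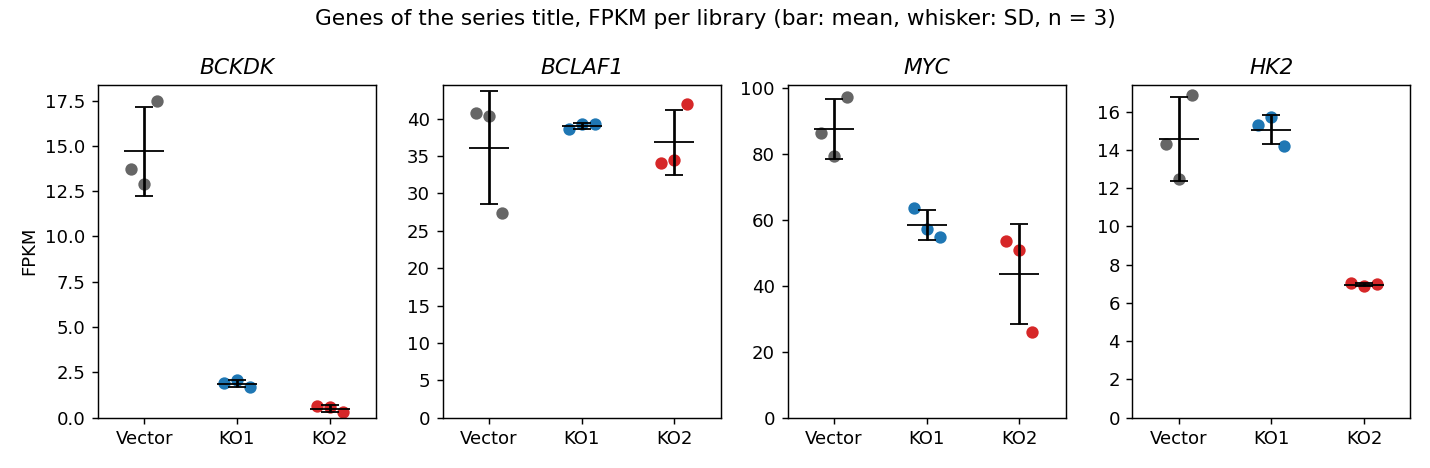
FPKM (vertical axis, starting at 0) of the 4 genes of the series title in each library of Vector, KO1 and KO2, with bars for the mean and whiskers for the SD of 3 libraries. BCKDK fell from a mean of 14.7 FPKM to 1.88 and 0.497, and HK2 fell to 6.96 FPKM in KO2 and stood at 15.1 FPKM in KO1.

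In KO1, 17 of 24 genes of cholesterol synthesis and 8 of 18 of fatty acid synthesis fell, while 11 of 16 amino acid transporters, 17 of 35 ATF4-linked genes and 14 of 21 ERK output genes rose. Camera called these 5 lists at the preset correlation and none with an estimated one (adjusted p = 0.245, 0.51, 0.245, 0.474 and 0.304). FASN, the fatty acid synthase, fell from 206 ± 97 to 46.5 ± 3.02 FPKM (log2 -2.03, limma adjusted p = 0.000442) although its neighbours had a median of 0.49. IL11, a cytokine, rose from 0.484 ± 0.412 to 20.3 ± 1.21 FPKM (log2 3.88, limma adjusted p = 4.12e-06; neighbours 0.66). Over all 16426 genes, 2865 rose and 2744 fell in KO1 against Vector by limma at a Benjamini-Hochberg adjusted p under 0.05, and 541 and 679 of these by at least 1 on the log2 scale. With scaling by library size alone 2214 rose and 3289 fell, with neighbours' medians subtracted 2153 and 2846, and with the GC and length trend removed 3380 and 4015. Leaving out 1 library gave between 3705 calls (without KO1 replicate 2) and 7367 (without Vector replicate 3), and leaving out both libraries that stood apart gave 9335.

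Of 24 measured genes of cholesterol synthesis, 1 rose and 17 fell in KO1 (1 and 18 adjusted over the list alone; camera adjusted p = 2.15e-07, and 0.245 with an estimated correlation). HMGCS1, which makes HMG-CoA for the pathway, fell from 39.6 ± 7.49 to 9.68 ± 0.779 FPKM (log2 -1.91), and INSIG1, a sterol-regulated inhibitor of SREBP processing, fell from 41.4 ± 3.6 to 12.1 ± 0.177 FPKM (log2 -1.69). PMVK was the member that rose (log2 0.65), a call lost in 7 of the 9 fits that left out 1 library (highest adjusted p = 0.14, without Vector replicate 2). TM7SF2 had a value of -0.39 that missed the threshold. Of 18 genes of fatty acid synthesis and desaturation, 1 rose and 8 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.00882, and 0.51 with an estimated correlation). The desaturase SCD fell from 1240 ± 23.2 to 369 ± 4.16 FPKM (log2 -1.74), ACLY, which makes cytosolic acetyl-CoA, fell by 1.05, and SCD5 rose by 1.03. FADS2 had a value of 0.3 that did not pass. In KO2 3 cholesterol synthesis genes rose and 4 fell, and 3 fatty acid synthesis genes rose and 7 fell. Neither list was called there (camera adjusted p = 0.973 and 0.71, and 0.991 for each with an estimated correlation).

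Of 16 amino acid transporters, 11 rose and 1 fell in KO1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000966, and 0.245 with an estimated correlation). SLC6A9, a glycine transporter, rose from 0.849 to 5.96 FPKM (log2 1.91), SLC43A2 rose by 0.67 and SLC43A1 fell by 0.8, with neighbours at 0.4 and 0.41. SLC38A1 stood at -0.09 without passing. In the list of ATF4 and amino acid response genes 17 of 35 rose and 4 fell (21 and 5 adjusted over the list alone; camera adjusted p = 0.00745, and 0.474 with an estimated correlation). GPT2, an alanine transaminase, rose by 1.12 and the cystine transporter subunit SLC7A11 by 1.35. In contrast, CEBPG fell by 0.95 beside neighbours at -0.79 and ALDH1L2 fell by 0.6 beside neighbours at -0.31. Of 21 ERK pathway output genes 14 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.23e-05, and 0.304 with an estimated correlation). EMP1 rose from 27.4 ± 2.27 to 153 ± 1.31 FPKM (log2 2.44; neighbours 0.4). The feedback regulators SPRY1 (0.3) and DUSP5 (-0.32) and the AP-1 subunit FOSL1 (0.22) did not pass in KO1.

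Of 19 interferon response genes 1 rose and 9 fell in KO1 (2 and 9 adjusted over the list alone; camera adjusted p = 0.00688, and 0.245 with an estimated correlation). Of 13 antigen presentation genes 0 rose and 6 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.00745, and 0.474 with an estimated correlation). SAMD9 fell by 1.73 (neighbours -0.62) and IFIT3 by 1.36. IRF7, an interferon regulatory factor, rose by 0.93 (neighbours 0.38) and DDX58 (0.43) did not pass. The immunoproteasome subunit PSMB8 fell by 1.75 and HLA-B, which shares sequence with other HLA genes, by 1.62. TAPBP and ERAP1 each stood at -0.11 without passing. Of 22 mesenchymal genes 7 rose and 1 fell in KO1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0293, and 0.474 with an estimated correlation). TNC, a matrix glycoprotein, rose from 1 ± 0.144 to 36.8 ± 0.304 FPKM (log2 4.24) and the matrix protease MMP2 from 0.0633 to 4.07 FPKM (log2 2.25; neighbours 0.32). LOX fell by 0.99 and SPARC (0.23) did not pass. In KO2 5 interferon response genes rose and 3 fell, 3 antigen presentation genes rose and 2 fell, and 8 mesenchymal genes rose and 3 fell. None of these lists was called there (camera adjusted p = 0.973, 0.655 and 0.397, and 0.991, 0.991 and 0.875 with an estimated correlation).

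Of 22 p53 target genes 12 rose and 5 fell in KO1 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0477, and 0.304 with an estimated correlation). Of 28 apoptosis regulators 14 rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.0477, and 0.6 with an estimated correlation). Each of these list calls was lost in 4 of 9 fits that left out 1 library, with a highest camera adjusted p of 0.113 for p53 targets and 0.0952 for apoptosis regulators, both without Vector replicate 3. FDXR rose by 0.98 (neighbours 0.39) and the DNA repair gene XPC by 0.53 beside neighbours at 0.55, with XPC at -0.04 once that median was subtracted. FAS fell by 0.6 and RRM2B by 0.48, beside neighbours at -0.21 and -0.31. Each of these calls was lost in 5 of 9 such fits (highest adjusted p = 0.0754 without Vector replicate 1 and 0.0924 without Vector replicate 2). BMF, a BH3-only death gene, rose by 1.07, BID fell by 1.05 and APAF1 by 0.97 (neighbours of APAF1 -0.42). BCL2L11 stood at 0.03. In KO2 3 p53 targets rose and 3 fell, and 3 apoptosis regulators rose and 8 fell. Neither list was called there (camera adjusted p = 0.8 for each, and 0.991 for each with an estimated correlation). Among the remaining genes picked for KO1, GAS6, the AXL ligand, rose from 6.25 ± 1.76 to 62.1 ± 2.18 FPKM (log2 3.15; neighbours 0.6). KRT8, a keratin with many near copies, rose from 16.2 ± 3.65 to 120 ± 9.18 FPKM (log2 2.83), and CCDC9B rose by 2.6. APOE fell by 2.81, PTP4A3 by 2.77 and TRAPPC6A by 2.07.

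In KO2, 23 of 35 ATF4-linked genes, 24 of 39 genes of the G2 and M phases and 13 of 39 S phase genes fell, while 10 of 21 receptor tyrosine kinases and ligands and 4 of 9 WNT targets rose. Camera called these lists too at the preset correlation and none with an estimated one (adjusted p = 0.229, 0.679, 0.229, 0.679 and 0.541). GJB2, a gap junction protein, rose from 0.233 ± 0.0876 to 16.8 ± 2.43 FPKM (log2 3.84, limma adjusted p = 4.79e-07). By limma 2115 genes rose and 2471 fell in KO2 against Vector, and 441 and 470 of these by at least 1 on the log2 scale. With neighbours' medians subtracted 2293 rose and 2078 fell, and with the GC and length trend removed 3674 and 3128. A fit of the 6 KO2 and Vector libraries alone called 2963 genes. Leaving out 1 library gave between 3203 calls (without Vector replicate 1) and 6531 (without Vector replicate 3), and leaving out both libraries that stood apart gave 8138.

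In the list of ATF4 and amino acid response genes 0 of 35 rose and 23 fell in KO2 (0 and 24 adjusted over the list alone; camera adjusted p = 1.32e-07, and 0.229 with an estimated correlation). CEBPG, a partner of ATF4, fell from 70.2 ± 11.2 to 14 ± 0.411 FPKM (log2 -2.24; neighbours -0.92) and ALDH1L2 by 1.23. GPT2 (0.03) and SLC7A11 (-0.14) did not pass. Among 16 amino acid transporters 2 rose and 6 fell (2 and 6 adjusted over the list alone). The list was not called (camera adjusted p = 0.436, and 0.875 with an estimated correlation). SLC6A9 rose by 0.75 and SLC43A2 by 0.8, and the glutamine carrier SLC38A1 fell by 1.2 and SLC43A1 by 0.66.

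Of 39 genes of the G2 and M phases 0 rose and 24 fell in KO2 (0 and 24 adjusted over the list alone; camera adjusted p = 3.73e-06, and 0.679 with an estimated correlation). Of 39 S phase genes 1 rose and 13 fell (2 and 18 adjusted over the list alone; camera adjusted p = 0.00299, and 0.229 with an estimated correlation). BUB1, a spindle checkpoint kinase, fell from 22.3 ± 2.36 to 12.3 ± 1.8 FPKM (log2 -0.81) and CKS2 by 0.83. CDC25B (-0.01) and BIRC5 (0.09) did not pass. POLD1, a DNA polymerase subunit, rose by 1.15 beside neighbours at 0.61. CCNE1, cyclin E1, fell by 1.14 beside neighbours at -1.21, which left 0.09 when that median was subtracted. The replication helicase subunit MCM4 fell by 0.48, and E2F1 stood at 0.58 without passing. Of 53 MYC target genes 1 rose and 17 fell (1 and 19 adjusted over the list alone; camera adjusted p = 0.00306, and 0.679 with an estimated correlation). EIF2S1, a translation initiation factor, fell by 0.89. MYBBP1A rose by 0.62, a call lost in 8 of 9 fits that left out 1 library (highest adjusted p = 0.0999, without Vector replicate 1; neighbours 0.28). ODC1 fell by 0.35, a call lost in 6 of 9 (highest adjusted p = 0.105, without Vector replicate 1).

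Of 21 receptor tyrosine kinases and ligands 10 rose and 3 fell in KO2 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00904, and 0.679 with an estimated correlation). The EGFR ligand TGFA rose from 1.14 ± 0.126 to 14.6 ± 0.515 FPKM (log2 2.87). The receptor AXL fell from 204 ± 33.4 to 70.5 ± 30.8 FPKM (log2 -1.59; neighbours -0.48), while GAS6 (0.38) and NRG1 (0.24) did not pass. Of 9 WNT targets 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0136, and 0.541 with an estimated correlation), among them BMP4 (log2 1.88) and DKK1 (0.73). LEF1 (0.12) and NKD2 (-0.09) did not pass. For the 21 ERK output genes 4 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.9, and 0.991 with an estimated correlation). SPRY1 rose from 3.35 ± 0.471 to 21.7 ± 4.09 FPKM (log2 2.37) and EMP1 by 0.69. DUSP5 fell from 61.8 ± 6.48 to 10.4 ± 2.06 FPKM (log2 -2.48; neighbours -0.33) and FOSL1 from 168 ± 24.7 to 48.5 ± 5.18 FPKM (log2 -1.76, against neighbours at 0.35). The remaining genes picked for KO2 were CLU (log2 2.45) and NR2F1 (2.16), which rose, and UPP1 (-2.47), SH3BGRL (-2.36) and the chemokine CXCL2 (-2.11), which fell. In KO1 7 receptor tyrosine kinases and ligands rose and 4 fell, and 2 WNT targets rose and 2 fell. Neither list was called in KO1 (camera adjusted p = 0.355 and 0.926, and 0.97 for each with an estimated correlation).

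Glycolysis and branched-chain amino acid genes moved both ways in both clones. Of 25 genes of glycolysis and lactate export 8 rose and 3 fell in KO1 (8 and 3 adjusted over the list alone; camera adjusted p = 0.317, and 0.97 with an estimated correlation). In KO2 4 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.557, and 0.991 with an estimated correlation). PKM, pyruvate kinase, rose by 0.53 in KO1 and 0.57 in KO2, and TPI1, which has many processed copies, by 0.86 and 0.44 (neighbours 0.38 in KO1). The glucose transporter SLC2A3 fell by 0.75 and 0.55, against neighbours at 0.46 in KO1. GPI fell by 1.02 and 0.9 beside neighbours at -0.73 and -0.83. The PKM call in KO1 was lost in 3 of 9 fits that left out 1 library (highest adjusted p = 0.0598, without KO1 replicate 1), and the TPI1 call in KO2 in 7 of 9 (0.117, without Vector replicate 2). Of 24 genes of branched-chain amino acid catabolism 3 rose and 3 fell in each clone (3 and 3 adjusted over the list alone in each; camera adjusted p = 0.924 and 0.973, and 0.97 and 0.991 with an estimated correlation). In each clone the median was above 0 (0.01 and 0.02) and the mean below it (-0.01 and -0.03), with camera pointing down. HSD17B10 rose by 0.79 in KO1 and 0.57 in KO2, and BCAT2, the mitochondrial branched-chain transaminase, by 0.5 and 0.47 beside neighbours at 0.48 and 0.51. MUT, the methylmalonyl-CoA mutase, fell by 0.53 and 0.88 (neighbours -0.46 in KO2) and ACAT1 by 0.66 and 0.63 (neighbours -0.28 and -0.41). The calls of BCAT2 were lost in 4 of 9 fits that left out 1 library in KO1 (highest adjusted p = 0.105, without KO1 replicate 1) and in 8 of 9 in KO2 (0.145, without Vector replicate 2). The HSD17B10 call in KO2 was lost in 7 of 9 (0.142, without KO2 replicate 1).

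Of 24 TCA cycle genes 3 rose and 6 fell in KO1 (5 and 6 adjusted over the list alone; camera adjusted p = 1, and 1 with an estimated correlation; the median was 0.1 and the mean -0.08). In KO2 2 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.223, and 0.875 with an estimated correlation). DLAT, a subunit of pyruvate dehydrogenase, fell from 19.5 ± 3.14 to 4.3 ± 0.28 FPKM in KO1 and 7.34 ± 0.437 FPKM in KO2 (log2 -1.94 and -1.28; neighbours -0.26 and -0.4). DLST fell by 0.62 and 0.61 beside neighbours at -0.81 and -0.35, and stood at 0.15 in KO1 with that median subtracted. PC, pyruvate carboxylase, rose by 0.97 in KO2 (neighbours 0.35) and SDHC by 0.48 in KO1 (neighbours 0.33), with 0.31 and 0.23 in the other clone, which did not pass. Of 49 nuclear-encoded genes of oxidative phosphorylation 10 rose and 2 fell in KO1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.317, and 0.97 with an estimated correlation). In KO2 0 rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.919, and 0.991 with an estimated correlation; the median was 0.01 and the mean -0.04). UQCRC1 rose by 0.86 and COX8A by 1.29 in KO1 (neighbours of COX8A 0.3), and their values in KO2, 0.5 and 0.61, did not pass. COX6B1 fell by 0.66 in KO1, a call lost in 3 of 9 fits that left out 1 library (highest adjusted p = 0.0634, without KO1 replicate 2), and by 1.01 in KO2, beside neighbours at -0.69 and -0.78.

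**Figure D2:**
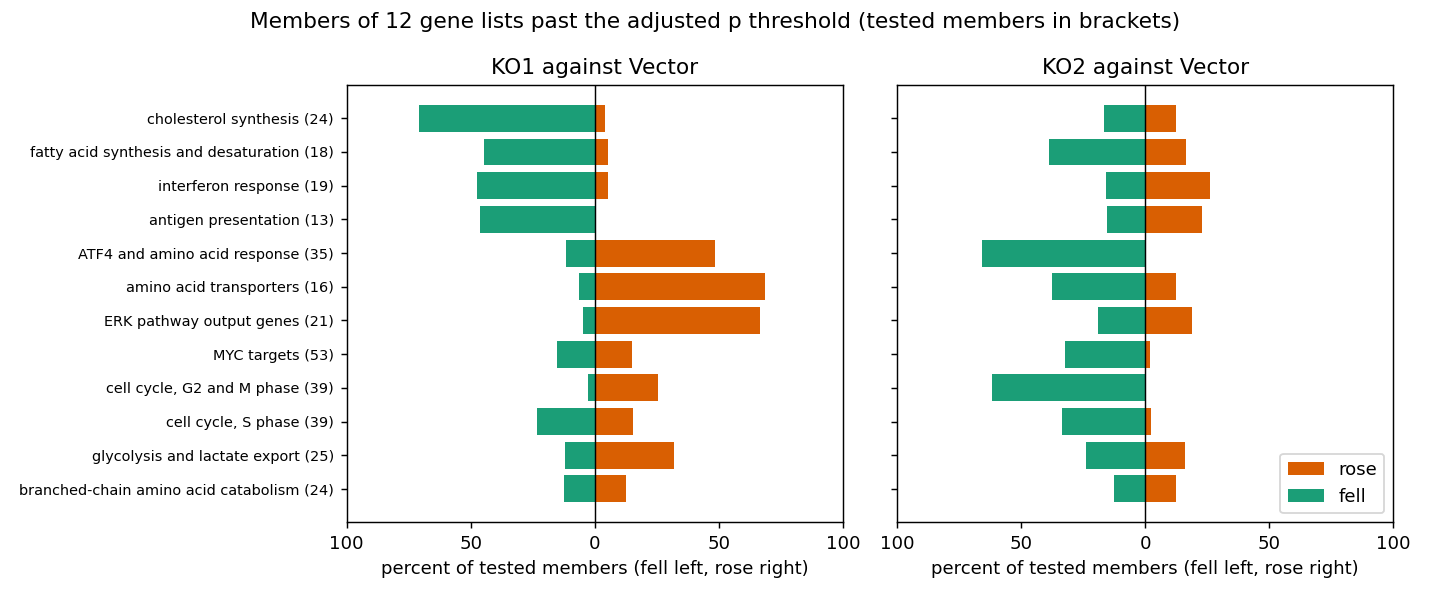
Percent of the tested members of 12 gene lists that fell (bars to the left) or rose (bars to the right) in KO1 and KO2 against Vector at a limma adjusted p under 0.05, with the number of tested members in brackets. Of 24 cholesterol synthesis genes 17 fell in KO1, and of 35 ATF4-linked genes 17 rose in KO1 and 23 fell in KO2; camera with an estimated correlation gave adjusted p of 0.245, 0.474 and 0.229 for these.

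Genes that changed the same way in both clones numbered 2197, with 979 that rose and 1218 that fell by limma, and 290 changed in opposite directions. Independent lists of these sizes would share 782 genes in the same direction (369 rising and 413 falling). In the simulations, unchanged groups and their shared control were all drawn as independent noise with each gene's fitted spread. They gave a mean of 0 such genes by limma, and 190 at an unadjusted p under 0.05 in both, where 3233 were observed. The real Vector libraries did not enter them, so a deviation across many genes, as in Vector replicate 3, is not represented. No gene changes in those simulations, so a mean of 0 calls follows from their design. The 3 Vector libraries cannot be split into 2 sets of 2, so part of the overlap may come from the shared controls. With KO1 as the reference in place of Vector, 2603 genes changed the same way in the other groups, and with KO2 as the reference 1835. The count of 2197 therefore does not tell a shared knockout effect from 3 groups that stand apart. Single-cell cloning, described for the knockout lines alone, would also be shared by both. Across genes, which are not independent replicates, the log2 fold changes of the clones had a Pearson r of 0.521 and a Spearman rho of 0.469, against 0.499 and 0.47 in the simulations. Their covariance was 0.165 against 0.0188 simulated, a difference of 0.146. The same sign was seen in 66.7% of genes, as in the simulations (66.7%). The simulated r and same-sign share follow from equal groups that share a control, whatever the data. Observed values near them therefore do not show that the clones agree no more than noise would. Leaving out 1 library gave from 1471 shared genes (without Vector replicate 1) to 3800 (without Vector replicate 3), and leaving out both libraries that stood apart gave 5171. The balance of directions moved with the setting. Without both libraries 2577 rose and 2594 fell, and without the low-value filter 766 rose and 1459 fell. At an absolute log2 fold change of at least 1 in each clone, 122 rose and 270 fell.

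The named genes that rose in both clones included the secreted proteins NOG, TGFA, FN1 and THBS1, and those that fell included the receptor IL13RA2 and the adaptor SHC1. NOG, the BMP antagonist noggin, rose from 0.742 ± 0.244 FPKM to 11.2 ± 0.695 in KO1 and 48.1 ± 9.48 in KO2 (log2 2.82 and 4.81, limma adjusted p = 3.21e-06 and 4.79e-07), above Vector in 6 of 6 knockout libraries. NRP1, a co-receptor for VEGF and semaphorins, rose from 0.463 to 19.3 and 8.07 FPKM, fibronectin (FN1) from 5.8 to 28.9 and 57.2 FPKM beside neighbours at 0.47 and 0.26, and TGFA from 1.14 to 9.17 and 14.6 FPKM. LPCAT2 rose by 2.86 and 2.6 (neighbours 0.32 in KO1). Further rises were seen for the clock transcription factor NPAS2 (2.47 and 2.35), CALB2 (2.74 and 2.22), THBS1 (2.56 and 2.11) and SORCS2 (2.5 and 2.07). IL13RA2, the decoy receptor for interleukin-13, fell from 38.1 ± 9.74 FPKM to 0.226 ± 0.0786 and 0.0348 ± 0.0603 (log2 -4.96 and -5.21, limma adjusted p = 3.56e-07 and 4.79e-07), below Vector in 6 of 6 knockout libraries. BCKDK itself was among the 10 falling genes. RBP7 fell by 4.14 and 3.62, the desmosomal cadherin DSG2 by 2.23 and 2.38 (neighbours -0.34 in KO2) and STEAP1 by 3.06 and 2.07 (neighbours -0.54 in KO1). ZNF300 fell by 3.98 and 1.74, and SHC1 by 1.62 and 2.01, against neighbours at 0.33 in KO1. ZNF781 fell by 1.84 and 1.94, ZNF302 by 2.13 and 1.71 and UQCRFS1, the Rieske subunit of complex III, by 1.55 and 1.64. These last 3 lie on chromosome 19, where neighbours stood at -0.55 and -0.68 for ZNF781, -0.71 and -0.85 for ZNF302, and -1.04 and -1.2 for UQCRFS1.

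Averaged over both clones against Vector, 2509 genes rose and 2634 fell by limma, and leaving out 1 library gave from 3375 calls (without Vector replicate 2) to 7030 (without Vector replicate 3). Leaving out both libraries that stood apart gave 8946, with 4551 rising and 4395 falling. Cyclin-dependent kinase inhibitors CDKN2B (log2 0.99 in KO1 and 0.84 in KO2) and CDKN2C (0.79 and 0.95) rose in both clones, and the collagenase MMP1 fell by 2.75 and 2.59 (neighbours -0.27 and -0.63).

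Setting KO2 against KO1 tests the difference between the clones, and it called 5079 genes, against 5609 for KO1 and 4586 for KO2 against Vector. IL11, GAS6, KRT8 and TNC were higher in KO1, and GJB2, NOG, PTP4A3 and HLA-B were higher in KO2. By limma 2386 genes were higher and 2693 lower in KO2 than in KO1, and with scaling by library size alone 2905 were higher and 1935 lower. With neighbours' medians subtracted the split was 2856 higher and 1994 lower, and with the GC and length trend removed it was 4355 and 3115, where the median of all genes moved to 0.12. Leaving out 1 library gave from 3337 calls (without KO1 replicate 1) to 6756 (without Vector replicate 3), and leaving out both libraries that stood apart gave 7834. Camera called 17 of 41 lists at the preset correlation and 0 with an estimated one. Of 35 ATF4-linked genes 0 were higher and 28 lower in KO2 (0 and 30 adjusted over the list alone; camera adjusted p = 1.07e-14, and 0.0895 with an estimated correlation). Of 24 cholesterol synthesis genes 17 were higher and 0 lower (18 and 0 adjusted over the list alone; camera adjusted p = 5.18e-09, and 0.0895 with an estimated correlation). Of 39 genes of the G2 and M phases 0 were higher and 23 lower (1 and 28 adjusted over the list alone; camera adjusted p = 2.01e-08, and 0.261 with an estimated correlation). KO1 had 10 rising and 1 falling gene of that list against Vector (10 and 1 adjusted over the list alone), or 9 and 8 with scaling by library size alone, and was not called (camera adjusted p = 0.317, and 0.97 with an estimated correlation).

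Neighbouring genes shifted together along several chromosomes. Among 109 protein-coding genes at 20 to 40 Mb of chromosome 19, the median log2 fold change was -0.71 in KO1 and -0.85 in KO2, with 92.7% and 93.6% of the genes below 0, and among 120 genes at 50 to 60 Mb of the same chromosome it was 0.66 and 0.62. Both clones also had lower medians at 0 to 10 Mb of chromosome 6 (-0.68 and -0.71, 29 genes) and at 40 to 50 Mb of the X chromosome (-0.54 and -0.54, 51 genes). Chromosome 14 stood at -0.56 in KO1 and -0.15 in KO2 (310 genes), chromosome 13 at 0.43 and -0.09 (163 genes), 90 to 130 Mb of chromosome 6 at -0.16 and -0.65 (78 genes), and 0 to 40 Mb of chromosome 16, which holds BCKDK, at 0.32 and -0.2 (218 genes). Over all 9607 such genes the medians were 0.06 and -0.02. Medians of the odd and the even genes of 275 bins of 10 Mb had a Pearson r of 0.817 in KO1 and 0.803 in KO2, where the highest of 1000 shuffles of gene positions gave 0.235 and 0.233. With the median of each gene's neighbours subtracted, 3470 of the 5609 calls in KO1 and 3071 of the 4586 in KO2 were still made.

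**Figure D3:**
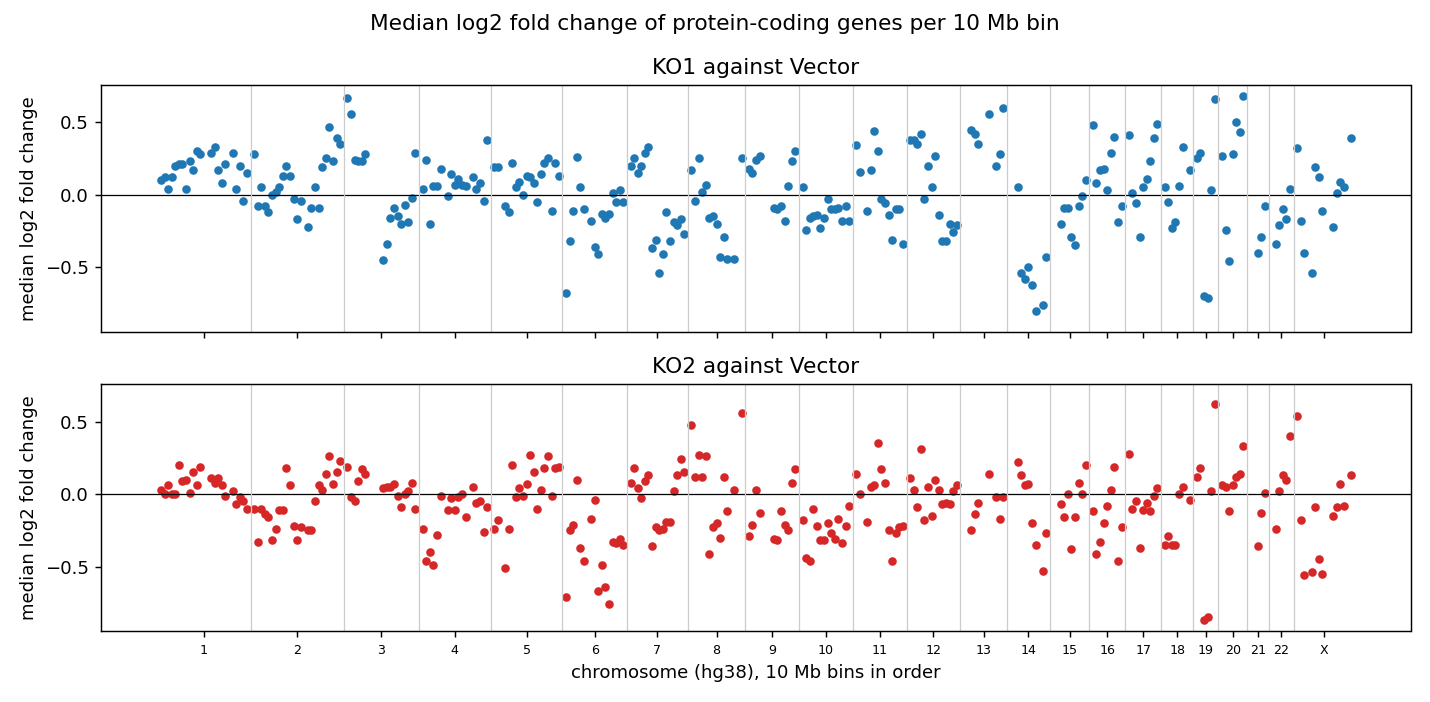
Median log2 fold change (vertical axis) of protein-coding genes in bins of 10 Mb, in chromosome order (horizontal axis), for KO1 and KO2 against Vector, with a line at 0. At 20 to 40 Mb of chromosome 19 the genes had medians of -0.71 and -0.85, and chromosome 14 stood at -0.56 in KO1 and -0.15 in KO2.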

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

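The alternatives that leave out Vector replicate 3 and KO2 replicate 3 together, subtract neighbours or remove the GC trend were chosen only after the main results were seen, as was the ATF4 pattern they are used on. A difference between the clones, tested as KO2 against KO1 by limma at an adjusted p under 0.05 or by camera for lists, picked out every result in this part.

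The clones differed in 5079 genes. All 10 splits of the 6 KO1 and KO2 libraries into groups of 3 were refitted, and 1 split, the real one, gave as many genes (6333 in a fit of those libraries, highest other 0 by limma, with up to 553 genes at an unadjusted p under 0.05). For KO1 against Vector the real split was likewise the 1 of 10 with as many by limma (5529, highest other 0, with up to 1006 at an unadjusted p under 0.05). For KO2 against Vector it was again the 1 of 10 (2963, highest other 0, with up to 2160 unadjusted). For the lists, 2 of 10 splits gave as many as the real one in KO1 against Vector (9, highest other 9), 5 of 10 in KO2 against Vector (6, highest other 10) and 1 of 10 in KO2 against KO1 (15, highest other 12). With 10 splits no share under 0.05 can be reached. For the mean of both clones 2 of the 84 splits gave as many genes, a share under 0.05 (real 2336, highest other 2999, in fits of 2 groups that pool both clones, where the fit of 3 groups called 5143). The higher one set KO1 apart from the rest and setting KO2 apart gave 1713, which points to 3 groups that stand apart from one another. The next split gave 231. Any of the 3 groups would thus reach a share under 0.05 among 84 splits, so this share does not single out Vector. For genes changed the same way in both clones 1 of 100 splits, the real one, gave as many (2197, highest other 1377). With KO1 taken as the reference in place of Vector, 2603 genes changed the same way in the other 2 groups, and with KO2 as the reference 1835. Neither of these was among the 100 splits, so the share of 1 in 100 does not single out Vector as the reference.

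Of 35 genes in the ATF4 and amino acid response list 17 rose and 4 fell in KO1 and 0 rose and 23 fell in KO2 (camera with an estimated correlation, adjusted p = 0.474 and 0.229), with a median KO2 minus KO1 difference of -1.03. Regional shifts and GC content or length are argued against as the cause of that difference. Its median was -0.86 with neighbours subtracted and -0.91 after the GC and length trend was removed. These tests compare the clones with each other, so they do not cover each clone's own change against Vector. Leaving out Vector replicate 3 and KO2 replicate 3 kept both calls at the preset correlation, with a larger camera adjusted p of 0.00424. The list's median was then 0.62 in KO1 and -0.5 in KO2, against 0.52 and -0.72 with all libraries. What stays open is whether the lists' genes are as independent as the preset correlation assumes, since camera with an estimated correlation gave 0.0895 for the difference. The clones also differ in how much BCKDK transcript is left, and a difference between single-cell clones that arose apart from BCKDK may account for it as well, which was not tested.

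Camera called 16 other lists between the clones at the preset correlation and none of them with an estimated one. Each is given as the median KO2 minus KO1 log2 difference with the estimated-correlation adjusted p. Lower in KO2 were amino acid transporters (-1.09, 0.0895), ERK pathway output genes (-0.75, 0.261), cyclin-dependent kinase inhibitors and senescence-linked genes (-0.63, 0.4), G2 and M phase genes (-0.48, 0.261) and apoptosis regulators (-0.4, 0.351). So were lysosome and autophagy genes (-0.35, 0.351), replication-dependent histones (-0.33, 0.53), cytosolic ribosomal proteins (-0.26, 0.787), glycolysis and lactate export (-0.26, 0.53) and MYC targets (-0.25, 0.261). Higher in KO2 were cholesterol synthesis (0.67, 0.0895), antigen presentation (0.53, 0.261), WNT targets (0.48, 0.261), heat shock genes (0.42, 0.261), fatty acid synthesis and desaturation (0.41, 0.333) and interferon response (0.32, 0.0985). The preset-correlation calls of ribosomal proteins (camera adjusted p = 0.72), histones (0.113) and WNT targets (0.0561) were lost without KO2 replicate 3, and that of glycolysis was lost in 6 of 9 fits that left out 1 library (0.0788 without KO2 replicate 2).

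Some genes of the title and some of those named for both clones differed between the clones. BCKDK differed by -0.95 and HK2 by -1.01, NRP1 by -1.17 and CALB2 by -0.52. NOG differed by 1.99, TGFA by 0.62, FN1 by 0.95, RBP7 by 0.52, STEAP1 by 0.99, ZNF300 by 2.24 and ZNF302 by 0.42. Genes picked for KO1 differed by -3.61 (IL11), -2.77 (GAS6), -2.81 (KRT8), -2.77 (CCDC9B), 2.29 (APOE), 3.39 (PTP4A3), 1.55 (TRAPPC6A) and 1.78 (FASN). Genes picked for KO2 differed by 4.09 (GJB2), 2.16 (CLU), 2.08 (SPRY1), 2.28 (NR2F1), -2.16 (DUSP5), -2.39 (UPP1), -1.93 (SH3BGRL) and -1.86 (CXCL2).

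Among the metabolic lists MUT differed by -0.35, TPI1 by -0.42, PC by 0.67 and DLAT by 0.65. The transporters SLC6A9 and SLC38A1 differed by -1.17 and -1.12, and the ATF4-linked genes GPT2 by -1.09, SLC7A11 by -1.49, CEBPG by -1.28 and ALDH1L2 by -0.63. Among lipid synthesis genes TM7SF2 differed by 1.84, INSIG1 by 1.43, HMGCS1 by 1.72, SCD by 1.23 and ACLY by 0.53. Signalling genes differed by -1.75 (EMP1), -1.98 (FOSL1), 1.33 (NRG1), -1.88 (AXL), 1.66 (BMP4), -1.17 (LEF1), 0.81 (NKD2) and 1.78 (DKK1). Cell cycle and growth genes differed by -1.65 (ODC1), 0.28 (MCM4), 0.54 (CCNE1), -0.91 (CDC25B), -0.51 (BIRC5) and -0.49 (BUB1). Matrix genes differed by -2.43 (TNC) and -0.94 (SPARC). In the p53 and apoptosis lists XPC differed by -0.28, RRM2B by 0.64, BMF by 0.8, BCL2L11 by 1.05, BID by 0.69 and APAF1 by 0.59. In antigen presentation TAPBP differed by 0.61, ERAP1 by 0.42, PSMB8 by 0.53 and HLA-B by 1.28. Lysosomal genes ATP6V0D1 and NPC1 differed by -0.36 and -0.67, the heat shock genes HSPA1B, HSPA1A and HSPA8 by 1.18, 1.22 and 1.03, and the histone HIST1H2BK by -0.66. Of these, the calls of CALB2, RBP7, ZNF302, MUT, TPI1, MCM4, BIRC5, BUB1, XPC, TAPBP, PSMB8, ATP6V0D1 and HIST1H2BK were each lost in at least 1 fit that left out 1 library, with highest limma adjusted p of 0.0689, 0.0652, 0.0929, 0.111, 0.144, 0.149, 0.0698, 0.0612, 0.113, 0.0577, 0.0532, 0.103 and 0.0769. XPC was also reversed to 0.2 with neighbours subtracted.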

How the results depend on the processing

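Results under library weights, protein-coding genes alone, neighbours subtracted, the GC and length trend removed, or Vector replicate 3 and KO2 replicate 3 both left out were computed after the data had been seen, and the rest was planned. For 275 named gene results, 6025 of 6599 values under other settings kept direction and side of the threshold, 546 lost the call, 12 gained it and 16 reversed. For 33 list results, 702 of 792 values kept the call, 90 lost it and 0 reversed. All 33 list calls were lost with camera at an estimated correlation. Apart from the title genes, only results called in the main fit were counted, so few could gain a call. The tallies therefore do not measure robustness in general. Both tallies include size factors recomputed from the recovered reads, which equalled the deposited scaling and kept all 275 gene results. The gene tally also includes the fold change threshold and treat, which use the main estimates and could not reverse a sign. Except where stated the cause was not tested. Calls with an absolute log2 fold change of at least 1 fell to 1220 (KO1), 911 (KO2), 1067 (KO2 against KO1), 714 (mean of both clones) and 392 (same direction in both). In the same order limma's treat against a 1.5-fold change gave 844, 565, 656, 542 and 282, since both ask for larger changes. A fit of the 6 libraries compared called 2963 genes in KO2. Camera with an estimated correlation called 0, 0 and 0 lists in KO1, KO2 and KO2 against KO1, with 5, 3 and 7 at an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 18, 18 and 26. Leaving out both libraries gave 9335, 8138, 7834, 8946 and 5171 genes and a correlation between the clones of 0.6. Of the calls with all libraries, 5523 of 5609 in KO1, 4299 of 4586 in KO2 and 4951 of 5079 between the clones were among them. Library weights, which were 0.106 for Vector replicate 3 and 0.163 for KO2 replicate 3, gave 10779, 10061, 9764, 10669 and 6266 genes and a correlation of 0.593. The correlation was 0.557 with limma-voom and 0.471 with the GC and length trend removed, which gave 3316 genes in the same direction. Leaving out 1 library gave 3705 to 7367 genes in KO1, 3203 to 6531 in KO2, 3337 to 6756 between the clones, 3375 to 7030 in their mean and 1471 to 3800 in the same direction, a correlation of 0.494 to 0.589, and 8 to 10, 6 to 8 and 14 to 18 lists. Leaving out Vector replicate 1 gave BCLAF1 0.23 in KO1 and 0.14 in KO2, and leaving out Vector replicate 3 gave HK2 0.16 in KO1, the highest such values. Values that reversed were BCLAF1 between the clones (0.02 by library size and 0.42 with neighbours subtracted, limma adjusted p = 0.0227) and HK2 in KO1 (-0.03 by library size, -0.04 without Vector replicate 2 and -0.08 with the GC trend removed). Reversed too were BCLAF1 in KO1 (-0.05 without Vector replicate 3, -0.05 without both libraries and -0.03 with weights) and BCLAF1 in KO2 (-0.14 without Vector replicate 3, -0.05 without KO2 replicate 3, -0.23 without both and -0.2 with weights). With neighbours subtracted the sign also turned for CCNE1 in KO2 (0.09), DLST in KO1 (0.15) and XPC in KO1 (-0.04) and between the clones (0.2). BCLAF1 in KO2 passed the test without both libraries (limma adjusted p = 0.00388) and with weights (0.0108), and in the other direction with neighbours subtracted (0.49, 0.0128), against 0.871 with all 9 libraries weighted equally. The replicate numbers gave no sign of pairing, since 1 of 9 libraries correlated best with its own number and pair correlations ran from -0.202 to 0.142. With few libraries per group and both replicates 3 of Vector and KO2 standing apart, this could not exclude pairing. With the replicate number as a block 4911, 3953, 4428, 4393 and 1827 genes were called. A negative binomial Wald test was not run, and limma-voom on the recovered reads called 5978 (KO1), 4975 (KO2) and 5501 (KO2 against KO1) genes. In simulated reads, where far fewer genes changed than were called here, 28.4% of 1.5-fold changes were recovered for KO1 against Vector.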

Other observations

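The test of the regional shifts on GC content used a stretch that was picked because its genes fell together. The other tests of these shifts, and the neighbours' medians given beside genes, were chosen after the patterns had been seen.

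Further lists had members that passed the limma test, while camera did not call them in the clones given here. Of 14 cyclin-dependent kinase inhibitors and senescence-linked genes 7 rose and 2 fell in KO1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.211, and 0.97 with an estimated correlation) and 2 rose and 5 fell in KO2 (2 and 6 adjusted over the list alone; camera adjusted p = 0.134, and 0.98 with an estimated correlation). Of 29 lysosome and autophagy genes 10 rose and 4 fell in KO1 and 3 rose and 10 fell in KO2 (10 and 4, and 5 and 10, adjusted over the list alone; camera adjusted p = 0.355 and 0.528, and 0.97 and 0.991 with an estimated correlation), with a median of 0.01 and a mean of -0.19 in KO2. NPC1, the lysosomal cholesterol transporter, fell by 0.63 and 1.3 (neighbours -0.21 and -0.32) and NPC2 by 1.33 and 1.01 (neighbours -0.76 and -0.35). ATG9A rose by 0.84 and 0.49 (neighbours 0.46 and 0.25; the KO2 call was lost in 4 of 9 fits that left out 1 library, highest adjusted p = 0.0737 without Vector replicate 2). ATP6V0D1 rose by 0.67 in KO1 (neighbours 0.32) and stood at 0.3 in KO2. Of 53 MYC targets 8 rose and 8 fell in KO1 (8 and 7 adjusted over the list alone; camera adjusted p = 0.945, and 0.979 with an estimated correlation), where ODC1, which makes putrescine, rose from 74.1 ± 5.81 to 184 ± 14.9 FPKM (log2 1.3). MYBBP1A rose by 0.62 there (lost in 5 of 9 such fits, highest adjusted p = 0.0897 without Vector replicate 2; neighbours 0.41), while EIF2S1 fell by 0.99 (neighbours -0.58) and MCM4 by 0.76.

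In KO1 the cell cycle genes CDC25B and BIRC5 rose by 0.9 and 0.6 (neighbours of BIRC5 0.43), CKS2 fell by 0.53 (lost in 4 of 9 fits that left out 1 library, highest adjusted p = 0.0755 without KO1 replicate 3) and BUB1 stood at -0.32. Of 39 S phase genes 6 rose and 9 fell in KO1 (6 and 9 adjusted over the list alone; camera adjusted p = 0.417, and 0.833 with an estimated correlation), with POLD1 (0.94, neighbours 0.66) and E2F1 (0.87) rising and CCNE1 (-1.67, neighbours -1.05) falling. NRG1 fell by 1.1 in KO1, NKD2 by 0.91 and DKK1 by 1.04, LEF1 rose by 1.29, and AXL (0.3) and BMP4 (0.22) did not pass. In KO2 TM7SF2 rose by 1.45 (neighbours 0.35), SCD5 by 1.2 and FADS2 by 0.46 (neighbours 0.29; lost in 4 of 9 such fits, highest adjusted p = 0.0927 without Vector replicate 1). ACLY fell by 0.52 there and SCD by 0.52 (lost in 4 of 9, highest adjusted p = 0.0729 without KO2 replicate 2), while PMVK (0.57), INSIG1 (-0.25) and HMGCS1 (-0.19) did not pass. In KO2 IRF7 and DDX58 rose by 0.94 and 0.66, SAMD9, IFIT3 and PSMB8 fell by 1.61, 1.21 and 1.22, and HLA-B stood at -0.35. TAPBP and ERAP1 rose by 0.5 and 0.3, calls lost in 7 of 9 such fits each (highest adjusted p = 0.114 without Vector replicate 1 and 0.0993 without KO2 replicate 2). TNC rose by 1.81 in KO2 and MMP2 by 2.42, and LOX fell by 1.01 and SPARC by 0.71. FDXR rose by 1 in KO2, BMF by 1.87 and BCL2L11 by 1.07. FAS fell there by 0.77 (neighbours -0.41), BID by 0.36 and APAF1 by 0.38 (lost in 7 and 3 of 9 such fits, highest adjusted p = 0.114 without KO2 replicate 1 and 0.0802 without Vector replicate 2), and XPC (0.25) and RRM2B (0.17) did not pass.

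Lists for handling, RNA class and other cell types gave these counts. Of 18 immediate-early genes 2 rose and 4 fell in KO1 and 3 rose and 4 fell in KO2 (camera adjusted p = 0.827 and 0.973, and 0.97 and 0.991 with an estimated correlation). In KO2 replicate 3 their median lay 0.75 below the other KO2 libraries, and in Vector replicate 3 it lay 0.36 above the other Vector libraries. Of 8 neuroendocrine markers 2 rose and 2 fell in KO1 and 3 rose and 2 fell in KO2 (camera adjusted p = 0.811 and 0.557, and 0.97 and 0.991 with an estimated correlation). Of 13 heat shock genes 0 rose and 2 fell in KO1 and 5 rose and 1 fell in KO2 (camera adjusted p = 0.827 and 0.106, and 0.97 and 0.679 with an estimated correlation). The near-identical HSPA1A and HSPA1B rose by 1.75 and 1.62 in KO2 and stood at 0.53 and 0.44 in KO1. HSPA8 fell by 1.32 in KO1 and stood at -0.3 in KO2. HSP90AB1 fell by 0.51 and 0.72 (the KO1 call was lost in 2 of 9 fits that left out 1 library, highest adjusted p = 0.0543 without KO1 replicate 2; neighbours -0.3 in KO2). Of 16 replication-dependent histones 4 rose and 2 fell in KO1 and 0 rose and 6 fell in KO2 (camera adjusted p = 0.724 and 0.134, and 0.97 and 0.875 with an estimated correlation). HIST1H1E and HIST1H2BK rose by 0.74 and 0.59 in KO1. HIST1H2BH fell by 0.39 and 0.63 and HIST1H2AE by 1.16 and 1.16 in KO1 and KO2, and all of these but HIST1H2BH in KO2 were lost in at least 1 such fit (highest adjusted p = 0.0753, 0.105, 0.126, 0.0843 and 0.0888). Of 52 cytosolic ribosomal protein genes 8 rose and 3 fell in KO1 and 2 rose and 4 fell in KO2 (camera adjusted p = 0.417 and 0.557, and 0.97 and 0.991 with an estimated correlation). RPL26 rose by 0.81 and 0.73 beside neighbours at 0.47 and 0.28 (the KO2 call was lost in 4 of 9, highest adjusted p = 0.0624 without KO2 replicate 1). RPS16 fell by 0.63 and 0.89 beside neighbours at -0.48 and -0.56, and RPL4 fell by 0.6 in KO1 (neighbours -0.35) and stood at -0.34 in KO2. Such genes have many processed copies.

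Whole stretches of chromosomes moved together in the clones, as at 20 to 40 Mb of chromosome 19. GC content and gene length are argued against as the whole cause, since the median nearer 0 of both clones was still -0.8 there after their trend was removed, and a change without regard to position by the odd and even correlation of 0.803. A copy number difference between the cell populations stays open, since copy number was not measured. At least 90.7% of the genes there were below 0 in each clone among both the lower and the higher expressed genes, but the stretch was picked because its genes fell together, so this decides nothing. UQCRFS1, GPI, CCNE1 and COX6B1 lie there, and why that stretch was lower in both clones was not settled.

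Vector replicate 3 and KO2 replicate 3 stood apart from their groups. A knockout library under the Vector label is argued against for Vector replicate 3 by its BCKDK value of 17.5 FPKM, above every knockout library, and by regional medians that correlated at 0.0669 with the other Vector libraries, -0.314 with KO1 and -0.146 with KO2, a narrow margin. For KO2 replicate 3 those correlations were 0.532 with its own group, -0.437 with KO1 and -0.19 with Vector. GC content and length explained 83.7% of the variance of the deviation of Vector replicate 3, whose medians ran from -0.41 in the GC-poorest of 4 sets of genes to 0.58 in the GC-richest, so a GC bias in that library is a likely cause. They explained 25.1% for KO2 replicate 3, which does not decide. That library had 9.77% mitochondrial reads against 5.94% and 5.99% in the rest of KO2. Its mitochondrially encoded mRNAs were higher by a median of 0.77, while nuclear-encoded genes of oxidative phosphorylation were lower (-0.31). Medians were also lower for ribosomal protein (-0.62), immediate-early (-0.75), senescence-linked (-0.43) and neuroendocrine marker genes (-0.56). No biological explanation was tested for either library.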
